A study of Caenorhabditis elegans with 2 samples.

How the data were processed

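Chromatin immunoprecipitation and sequencing was done by the authors, per the labels, on whole C. elegans young adults of the strain RW12226, synchronised by starving L1 larvae after bleaching and collected at 64.5 h. The strain carries pbrm-1 fused to TY1, EGFP and 3xFLAG tags at its own locus. Chromatin was sheared by sonication and immunoprecipitated with an antibody against GFP. The 2 biological replicates form 1 group, and the labels number them as separate biological replicates. The labels also name a control experiment, whose data were not used here.

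The files analysed here were 8 peak lists on the ce11 build, without header lines. For each replicate and for both replicates together there was a ranked list of all candidate peaks and a thresholded list, and for the series there were also a second ranked list and a conservative thresholded list. The aligner, peak caller, read filters and their versions are not given in the sources used here. The role of a further input named for the thresholded lists is not stated in the sources used here. The authors deposited a signal value for each peak, whose scaling is not given in the sources used here. The score was also made by the authors and deposited with each peak, and per the values it is a scaled irreproducible discovery rate (IDR) reaching 1000. The q value of each peak was deposited by the authors as −log10 of the caller's q, and the global IDR as −log10 as well. The lowest score of every thresholded list was 830, which corresponds in the same lists to an IDR of 0.01. Signal, score and q are the authors' own values and were used only to describe, rank or filter peaks within 1 list. In 1 series-level ranked list, 2 columns hold the signal of the 2 replicates without saying which column is which replicate, so they are described as the lower and the higher of the values. Read depth is unknown from peak lists, so no interval for depth is given and the numbers of peaks of the replicates cannot be set against their depths.

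The series list, thresholded from both replicates, was the main list, and each replicate's own thresholded list gave the replicate values. The 2917 peaks of the conservative list all occur in the ranked list that holds the signals of the 2 replicates. The 3243 peaks of the series list all occur in the other series-level ranked list. What was compared for the IDR of the series list is not known here, so it need not measure agreement between the replicates. Peaks were placed by their summits. Genes and transcripts came from Ensembl release 115 (WBcel235, the same assembly as ce11), and sequence came from the RefSeq copy of that assembly. Chromosome lengths were checked against the peak positions, and 0 peaks reached past a chromosome end. Only the 6 nuclear chromosomes were used. A gene was called bound when a summit lay within 1000 bp upstream to 200 bp downstream of the 5' end of any of its transcripts, and a summit counted for every gene whose window held it. Annotation classes were assigned in a fixed order with promoters first. The class past 3' ends reached 500 bp.

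Overlaps, annotation classes and gaps between genes were tested by circular shifts along each chromosome (100000 shifts, 10000 for noncoding RNA genes, 200 for the distance profile), which keep the spacing of peaks. The smallest p these shifts can give is 2.00e-05 in two-sided tests, 1e-05 in one-sided ones and 0.0002 for noncoding RNA genes. Overlap of replicates needed at least 1 bp. Densities on X and in autosome centres were tested with exact binomial tests and Clopper-Pearson intervals at 95%, which treat peaks as independent. Gene lists were tested with two-sided Fisher's exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over 30 lists at a threshold of 0.05. The lists were defined by gene name patterns and cover complexes, pathways, gene families and tissue markers. GC content was tested by sign flips of the paired differences, and 18 motifs by exact McNemar tests of summit windows reaching 100 bp to each side against a flank window centred 600 bp away. The McNemar test used 1 flank, its side drawn at random, while the flank shares and ratios are means of both sides. A motif call near the threshold can thus turn on the side drawn. The interval of the signal correlation came from 1000 bootstrap draws of peaks. Peaks and genes are not independent replicates, and with 2 replicates and 1 group there is no test between conditions.

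The gene lists, the motifs, the tests described above, the windows and the rule for named genes were fixed before the data were examined. The rule took the 10 peaks of largest signal, up to 4 bound members of largest signal in each list, every SWI/SNF subunit, and the 5 strongest peaks found in 1 replicate only. The members of the sperm list that this rule takes are not reported here by name. Other genes are named only where a count of 5 or fewer or a shared peak called for it. Alternatives tried were the conservative list, the peaks at or above the median signal, each replicate alone, narrower (500 to 100 bp) and wider (2000 bp) promoter windows, peak midpoints, nearest genes only, lists without genes that closely follow another on the same strand, rotation of the bound calls along the genome, lists matched on spacing, and other overlap rules. A filter on the caller's q value, the removal of peaks near tRNA genes, the count of all bound genes by nearest gene, the comparison of motifs with shuffled windows, the comparison of ribosomal protein genes with sarcomere and vitellogenin genes and the count of spliced leader loci were added after seeing the data. Lists matched on spacing were planned as an alternative, and their use to weigh gene spacing as a cause was chosen after seeing the data.

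The tests were first run on simulated data: 40 simulations of 3243 peaks placed at random, with and without planted effects, on 19973 genes. A planted excess in promoters, at tRNA genes and in a list of 50 genes with 40% of members bound was found in 100% of simulations. Without an effect, 2.3% of 1000 random lists passed at an unadjusted p of 0.05, and promoters passed in 2.5% of simulations. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.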

Results

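PBRM-1 is the polybromo subunit of the PBAF form of the SWI/SNF complex, which moves and evicts nucleosomes. Its binding sites were mapped by chromatin immunoprecipitation and sequencing in whole Caenorhabditis elegans young adults, 64.5 h old. The worms carried the pbrm-1 gene on chromosome I with an EGFP tag added by genome editing, and the chromatin was pulled down with an antibody against GFP. There was 1 group with 2 biological replicates, so the design holds no contrast between conditions, and the question addressed is where in the genome PBRM-1 sits at this stage. The list made from both replicates, called the series list here, held 3243 peaks with a median width of 320 bp, covering 977 kb. Replicate 1 had 1370 peaks in its own list and replicate 2 had 2173. Read depth is unknown from peak lists. All positions are on the ce11 build and counted from 1.

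The strongest sites recurred in both replicates. Of the replicate 1 peaks, 1143 (83.4%) overlapped a replicate 2 peak, against a mean of 1.17% after circular shifts along the chromosomes. Of the replicate 2 peaks, 1135 (52.2%) overlapped a replicate 1 peak, against 0.737%. Each overlap had the smallest p that 100000 shifts can give (one-sided permutation p = 1e-05). Of the series list, 1127 peaks were in both replicates' own lists, with a median signal of 161.5, and 1052 (32.4%) were in neither, with a median signal of 70.1. Across 3226 peaks with a signal value for each replicate, Spearman's rho was 0.601 (95% bootstrap interval 0.574 to 0.628) and Pearson's r was 0.902. These correlations run across peaks, which are not independent replicates. The conservative list shares 2527 (77.9%) of the series peaks, and it was selected by IDR among the peaks that hold these 2 signals. Part of the correlation, in either list, may thus follow from that selection. Over all 89171 ranked peaks, most of them weak, rho was 0.334. In the series list, 760 peaks (23.4%) had a q value above 0.05 from the authors' peak caller.

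PBRM-1 summits were enriched in the promoter windows of protein-coding genes. Promoter windows, from 1000 bp upstream to 200 bp downstream of an annotated 5' end, held 1690 of 3243 summits (52.1%), against 25.9% ± 0.834 (SD over shifts). The share was 52.5% in replicate 1 and 55.4% in replicate 2. Introns held 15.1% of summits against 27.9% after shifts, coding exons 6.14% against 18.9%, and intergenic sequence 11.2% against 20.5%. The 500 bp past the 3' ends of genes held 8.02% against 3.41%, and noncoding RNA genes held 4.26% against 0.598%. Each of these 6 differences had an adjusted permutation p of 2.67e-05, the smallest the shifts can give (two-sided permutation test, Benjamini-Hochberg over 8 classes). The 3' UTR share of 2.96% lay above the 2.36% after shifts (adjusted permutation p = 0.0439), but this excess was not stable. It passed in the conservative list (3.15% against 2.37%, adjusted permutation p = 0.0122), without peaks near tRNA genes (3.29% against 2.33%, 0.00215) and with peak midpoints (0.0441). The share lay below the shifts in replicate 1 alone (1.68%) and replicate 2 alone (2.12%), neither passing, and passed below them in the peaks at or above the median signal (1.36% against 2.38%), while no difference passed with the q filter (2.38%) or with narrower or wider promoter windows (adjusted permutation p = 0.130 and 0.420). The 5' UTR share of 0.216% against 0.414% did not pass (adjusted permutation p = 0.102). Coding exons held smaller shares of replicate 1 (2.41%), of replicate 2 (3.31%) and of the peaks at or above the median signal (1.60%), and the deficit passed in each.

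**Figure D1:**
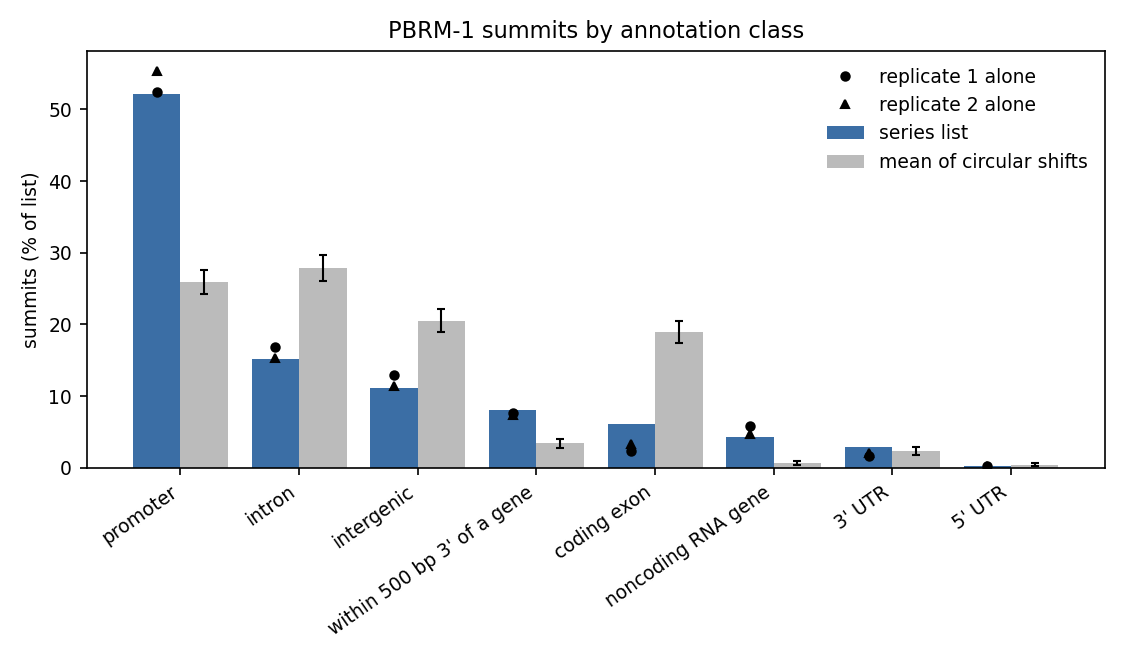
Share of PBRM-1 summits (percent of each list, y axis) in 8 annotation classes. Blue bars are the series list of 3243 peaks, grey bars the mean of circular shifts with the range that holds 95% of shifts, and points the list of each replicate alone; promoters hold 52.1% of summits against 25.9% after shifts.

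Summits clustered 100 to 200 bp upstream of 5' ends. That interval held 336 summits, against 75.3 on average after shifts, the highest count of any 100 bp bin. The median distance to the nearest protein-coding 5' end was 631 bp, 45.6% of summits lay within 500 bp of one against 22.9% after 200 shifts, and 61.5% lay on the upstream side. Among 1932 summits in gaps between protein-coding genes, 810 (41.9%) lay between divergent neighbours, which share an upstream region, against 34.5% after shifts (adjusted permutation p = 6.00e-05, two-sided, 3 gap kinds). Tandem gaps held 48.6% against 54.4% (adjusted permutation p = 6.00e-05). Convergent gaps, which hold no 5' end, held 9.47% against 11.1%, which did not pass (adjusted permutation p = 0.0606); the deficit passed among the peaks at or above the median signal (8.79%, adjusted permutation p = 0.0275), in replicate 2 alone (8.56%, 0.00698), with a filter on the caller's q value (9.25%, 0.0390) and without peaks near tRNA genes (8.57%, 0.00462), and did not pass in the conservative list (9.40%, 0.0651) or in replicate 1 alone (9.03%, 0.0841).

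**Figure D2:**
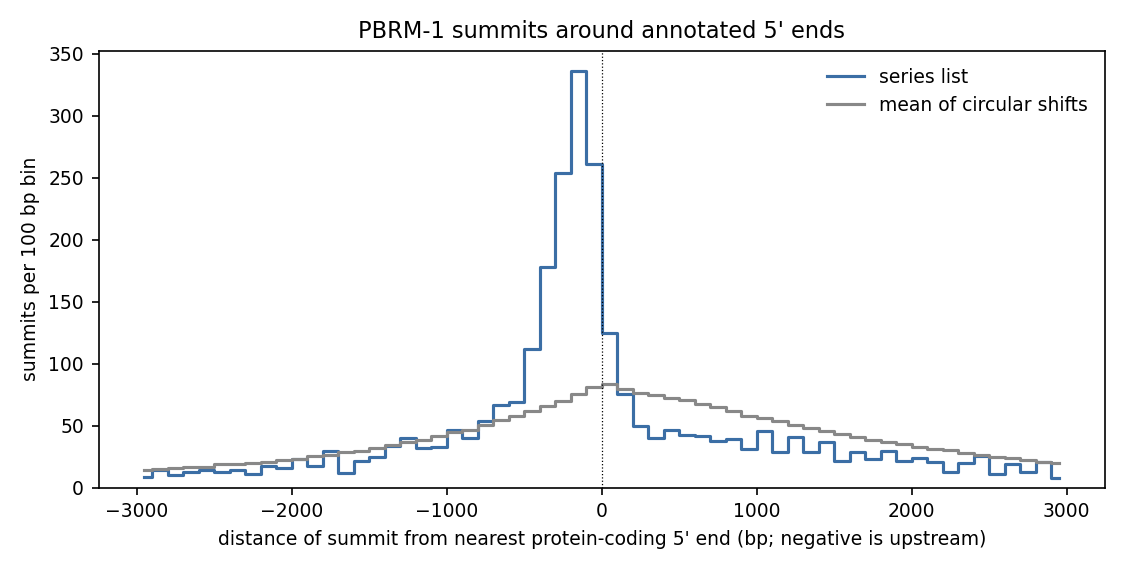
Number of PBRM-1 summits per 100 bp bin (y axis) by distance from the nearest annotated protein-coding 5' end in bp (x axis, negative values upstream). The blue line is the series list and the grey line the mean of 200 circular shifts; the series list peaks at 336 summits 100 to 200 bp upstream, where shifts give 75.3.

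The 10 strongest peaks were in both replicates' own lists, and 8 of them had their summits in promoter windows. The strongest, with a signal of 1562, lay in the promoter of egg-5 at I:4171959-4172594, also within 500 bp of the spliced leader gene sls-2.4. egg-5 encodes a pseudophosphatase of the egg-to-embryo transition. Next came the promoter of rpl-3, a large ribosomal subunit protein, at III:3867424-3867715 (signal 1412). An intron of max-2, which encodes a p21-activated kinase, followed at II:13016442-13016755 (1408). The promoter of H41C03.3 at II:5844635-5845065 (1408) lay beside the spliced leader gene sls-2.1. An intron of ckk-1, which encodes a calcium/calmodulin-dependent kinase kinase, held a peak at III:5637322-5637652 (1343). The shared upstream region of the histone genes his-67 and his-68 and of alg-5, an Argonaute gene, held a peak at I:9988798-9989185 (1218). The remaining peaks lay in the promoters of K07C5.13 at V:10341846-10342312 (1169), of tasp-1 and K01G5.10 at III:10759104-10759399 (1142), of 2 neighbouring genes at IV:15646429-15646884 (973), and of rpl-15 and K11H12.8 at IV:654785-655063 (912). The signal is the authors' own value, and at each of these 10 peaks both replicates' signals were above 340.

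Of 19973 nuclear protein-coding genes, 1968 (9.85%) had a summit in a promoter window and are called bound here. Replicate 1 alone gave 924 bound genes, replicate 2 alone gave 1523, and 826 were bound in both. A summit in a promoter window fell into the windows of more than 1 gene in 497 of 1690 cases, so a bound neighbour can carry a gene into the count. Among 30 gene lists fixed beforehand, 13 were bound more often than other genes, 8 less often, and 9 did not pass (two-sided Fisher's exact tests, Benjamini-Hochberg over 30 lists). Genes are not independent replicates, and these tests compare genes within 1 peak list.

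Ribosomal protein genes had the highest odds ratio of the 30 lists. Of 83 ribosomal protein genes, 64 (77.1%) were bound, against 9.57% of other genes (odds ratio 31.8, 95% interval 18.8 to 56.3, adjusted exact p = 1.79e-46); 44 were bound in replicate 1 and 62 in replicate 2. With each summit given to its nearest gene only, 44 (53.0%) were bound (odds ratio 13.9, adjusted exact p = 2.80e-26). After rpl-3 and rpl-15, the strongest were rpl-35 (signal 883, peak at III:7854560-7854821) and rpl-20 (822, at IV:4749948-4750207). Translation factors were bound in 14 of 39 cases (odds ratio 5.15, adjusted exact p = 2.72e-05), led by iff-2, an eIF5A gene (478), the elongation factor gene eef-2 (338) and the initiation factor genes eif-3.C (325) and eif-2Bgamma (264). Splicing factor genes were bound in 15 of 37 cases (odds ratio 6.28, adjusted exact p = 2.61e-06), led by the Sm protein gene snr-4 (631) and prp-19 (253); the SR protein genes rsp-1 and rsp-2 share 1 peak (231) at II:11453128-11453269.

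Genes of energy metabolism and of protein folding and turnover were also bound more often than other genes. Oxidative phosphorylation genes were bound in 21 of 44 cases (odds ratio 8.43, 95% interval 4.43 to 15.97, adjusted exact p = 1.07e-09), among them the cytochrome c oxidase subunit genes cox-5A (signal 622), cox-5B (480) and cox-6B (238) and the ATP synthase gene atp-1 (353). Chaperone genes were bound in 22 of 62 cases (odds ratio 5.08, adjusted exact p = 2.25e-07; 8.58 in replicate 1 alone and 6.28 in replicate 2 alone), led by the chaperonin genes cct-8 (607) and hsp-60 (596), dnj-13 (478) and the Hsp70 gene hsp-1 (434). With nearest genes only, 10 of the 62 were bound (odds ratio 2.32, adjusted exact p = 0.0410). Proteasome genes were bound in 10 of 33 cases (odds ratio 3.99, adjusted exact p = 0.00200), led by rpn-3 (264), rpn-9 (157), rpn-11 (135) and rpt-6 (130). The chaperone gene hsp-110 had the same signal as rpn-3, and the histone gene his-72 the same as rpt-6, so these peaks are likely shared. The proteasome call was lost in the conservative list (odds ratio 2.26, adjusted exact p = 0.150) and in replicate 2 alone (2.70, adjusted exact p = 0.0607).

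Genes of the cell cycle and DNA replication list were bound in 20 of 60 cases (odds ratio 4.61, adjusted exact p = 1.95e-06). The list takes in every gene named cdc or mcm, whatever its role. The strongest were cdc-48.1, an AAA ATPase gene (signal 835), pcn-1, which encodes the replication clamp PCNA (365), efl-1, an E2F factor gene (323), and lin-23 (246). Core and linker histone genes were bound in 25 of 80 cases (odds ratio 4.20, 95% interval 2.50 to 6.87, adjusted exact p = 4.28e-07), led by his-67 and his-68 (1218), his-37 (439) and the linker histone gene his-24 on X (393). Histone genes are near-identical copies in clusters, so reads may be split between them, and the assignment to single members is uncertain.

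Genes of chromatin regulators were themselves bound. Of 54 chromatin regulators outside the SWI/SNF complex, 25 (46.3%) were bound (odds ratio 7.98, 95% interval 4.47 to 14.1, adjusted exact p = 5.88e-11); 14 were bound in replicate 1 and 15 in replicate 2 (odds ratios 7.31 and 4.70). The strongest were set-16, a histone methyltransferase gene (signal 823, at III:13643594-13643876), lin-54 (485) and lin-53 (407), both of the DREAM complex, and cbp-1, a histone acetyltransferase gene (397). The lin-54 peak also lay in the promoter of rpl-12, a ribosomal protein gene. Of 13 SWI/SNF subunit genes, 5 were bound (odds ratio 5.73, 95% interval 1.47 to 19.9, adjusted exact p = 0.0107), 4 of them in each replicate's own list (odds ratios 9.20 and 5.40). They were swsn-3 (185, at III:2768680-2768999), swsn-6 (165, at IV:5394768-5395087), pbrm-1 itself (150), swsn-7 (115, at II:8028297-8028616) and swsn-1 (65.7, at V:20249722-20250041), the last in neither replicate's list. The pbrm-1 peak at I:7500364-7500683 lay inside the gene, which spans I:7495436-7503582, at the 5' end of an internal transcript. let-526, swsn-4, swsn-9, snfc-5, swsn-2.2, dpff-1, phf-10 and ham-3 were not bound. The SWI/SNF call was lost with a promoter window of 500 bp upstream to 100 bp downstream (odds ratio 3.68, adjusted exact p = 0.104).

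Oocyte and germ line genes were among the lists bound more often. Of 34 oocyte and egg genes, 16 (47.1%) were bound (odds ratio 8.19, 95% interval 3.90 to 17.04, adjusted exact p = 1.75e-07); 9 were bound in replicate 1 and 17 in replicate 2. After egg-5 the strongest were chs-1, the eggshell chitin synthase gene (signal 273), mex-1 (243) and cpg-1, which encodes an eggshell chondroitin proteoglycan (236). The egg-5 peak also lay beside the spliced leader gene sls-2.4, so it may not belong to egg-5. Of 57 germ line genes, 14 (24.6%) were bound (odds ratio 2.99, adjusted exact p = 0.00204), led by the synaptonemal complex genes syp-4 (315) and syp-3 (128), the cohesin gene coh-3 (135) and hrde-1, a nuclear Argonaute gene (126). Sperm genes went the other way, with 3 of 101 bound (odds ratio 0.279, adjusted exact p = 0.0260). None of the bound sperm genes was bound in replicate 1, and the sperm call was lost in the conservative list (odds ratio 0.309, adjusted exact p = 0.0525) and in replicate 2 alone (0.370, adjusted exact p = 0.133).

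Insulin and TOR signalling genes were bound in 6 of 21 cases (odds ratio 3.67, adjusted exact p = 0.0212). rheb-1, a small GTPase gene upstream of TOR, had a peak with a signal of 276 in both replicates' lists at III:9456239-9456398. Those of akt-2 (94.3), pptr-1 (81.7) and raga-1 (81.4) were in neither. Each replicate alone gave 1 bound gene, with odds ratios of 0.605 and 1.03, so this call rests on peaks that only the combined list holds. It was also lost in the conservative list (3.17, adjusted exact p = 0.0525) and among the peaks at or above the median signal (1.65, adjusted exact p = 0.440).

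**Figure D3:**
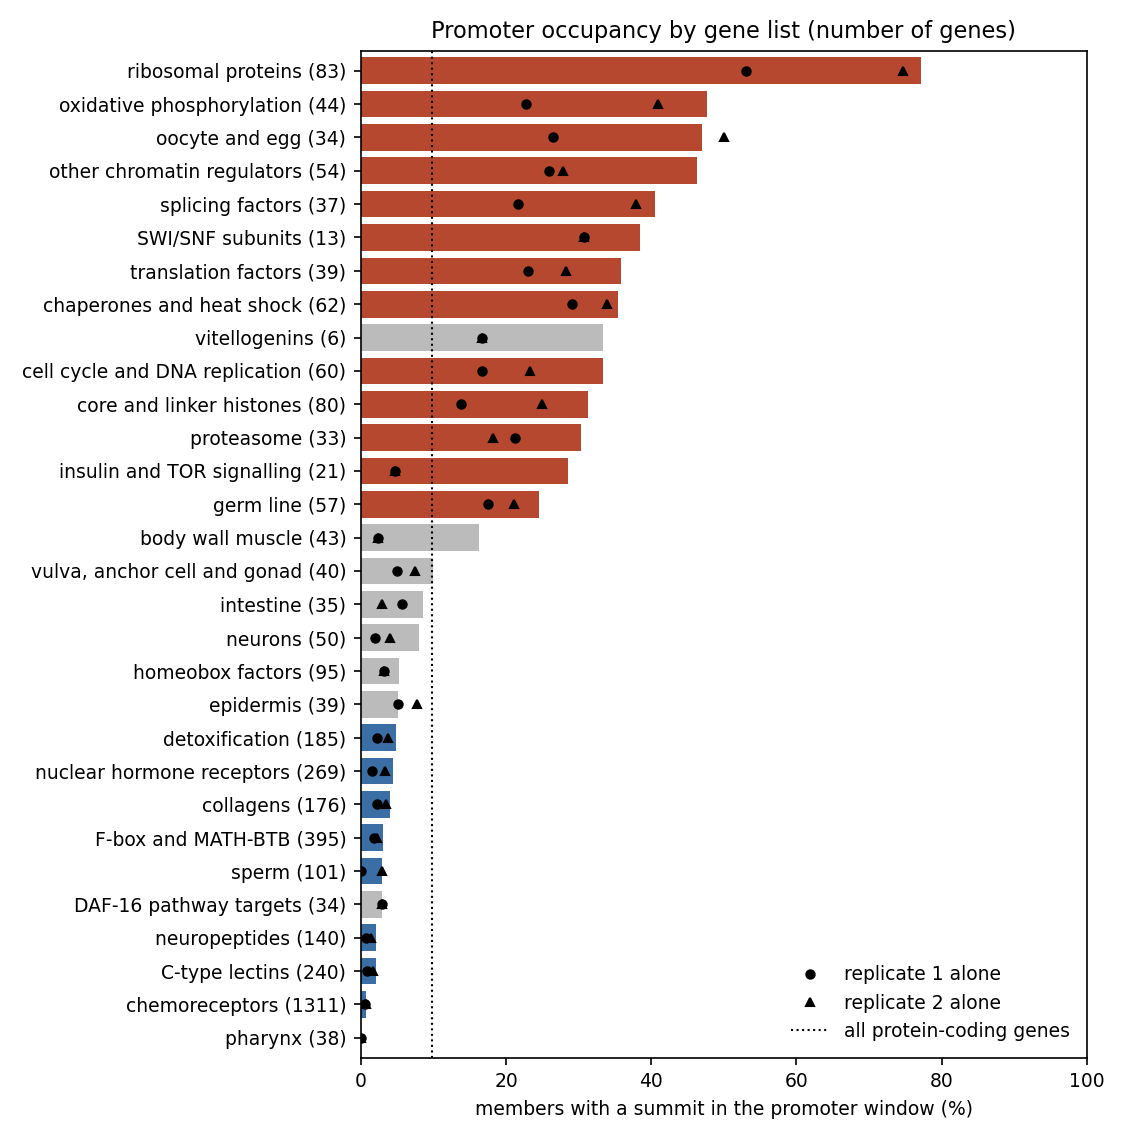
Percent of the members of 30 gene lists with a PBRM-1 summit in the promoter window (x axis), with the number of genes of each list in parentheses. Bars are the series list (red, bound more often than other genes; blue, less often; grey, not passing at an adjusted p of 0.05), points each replicate alone and the dotted line all protein-coding genes (9.85%); ribosomal protein genes reach 77.1% and chemoreceptors 0.763%.

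Large families of sensory, environmental and cuticle genes were rarely bound. Of 1311 chemoreceptor genes, which encode G protein-coupled receptors, 10 (0.763%) were bound against 10.5% of other genes (odds ratio 0.0656, 95% interval 0.0313 to 0.121, adjusted exact p = 3.34e-45), with odds ratios of 0.119 in replicate 1 alone and 0.0783 in replicate 2 alone. Their strongest peaks were at sri-5 (signal 262), srh-16 (198), srh-269 (185) and sre-23 (169). F-box and MATH-BTB genes were bound in 12 of 395 cases (odds ratio 0.282, adjusted exact p = 8.50e-07), C-type lectin genes in 5 of 240 (0.193, adjusted exact p = 8.69e-06) and neuropeptide genes in 3 of 140 (0.199, adjusted exact p = 0.00128). The neuropeptide genes were ins-39 (188), flp-23 (88.8) and ins-37 (86.8). Among F-box genes, fbxa-83 had a strong peak (643), while the peak of fbxa-90 (323) is the one that also lay in the promoter of efl-1. Nuclear hormone receptor genes were bound in 12 of 269 cases (odds ratio 0.424, adjusted exact p = 0.00343), led by nhr-47 (320), whose peak also lay in the promoter of the chaperone gene dnj-19, and nhr-255 (246). Collagen genes, which encode the cuticle, were bound in 7 of 176 cases (0.377, adjusted exact p = 0.0117), led by col-63 (413) and col-185 (195), and this call was lost in each replicate alone (0.425 and 0.477). Detoxification genes were bound in 9 of 185 cases (0.465, adjusted exact p = 0.0260), among them ugt-40 (245) and cyp-43A1 (243), and this call too was lost in each replicate alone (0.453 and 0.474).

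The remaining 9 lists, most of them of somatic tissues, did not pass at this threshold. None of 38 pharynx genes was bound (adjusted exact p = 0.0663, and 0.0190 with a window reaching 2000 bp upstream). Neuron genes were bound in 4 of 50 cases (odds ratio 0.795, 95% interval 0.208 to 2.18), with a peak in both replicates' lists only at unc-31 (signal 436). The unc-31 peak at IV:12786993-12787199 lay inside the gene, which spans IV:12773867-12788354, and counted through an internal transcript. Intestine genes were bound in 3 of 35 cases (0.857, interval 0.168 to 2.74), namely fat-6, cpl-1 and spl-1. Replicate 1 alone gave 2 bound intestine genes among 924 bound genes in all. Replicate 2 alone gave 1 among 1523, so the direction of the intestine list is not settled. Epidermis genes were bound in 2 of 39 cases (0.494), namely ajm-1 and wrt-1, and vulva, anchor cell and gonad genes in 4 of 40 (1.02), led by egl-17 (137) and unc-40 (133). Although the single replicates gave fewer bound genes in all, replicate 1 alone gave 2 bound epidermis genes and replicate 2 alone gave 3. The direction of the epidermis list is thus not settled. Body wall muscle genes were bound in 7 of 43 cases (1.78, interval 0.668 to 4.07), where the actin gene act-2 (177) was the one in both replicates' lists among the 4 strongest. Each replicate alone gave 1 bound muscle gene, with odds ratios of 0.490 and 0.288, so the direction of this list is not settled. The yolk protein genes vit-2 and vit-5 were bound out of 6 vitellogenins (4.58, interval 0.414 to 31.96). Homeobox genes were bound in 5 of 95 cases (0.507), led by ceh-38 (172) and ceh-43 (106), and targets of the transcription factor DAF-16 in 1 of 34 (0.277), at lea-1. The peaks of fat-6, ajm-1 and lea-1 also lay inside their genes and counted through internal transcripts. The intervals are wide, so differences of moderate size could not be told from none in these 9 lists.

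Genes for small noncoding RNAs carried PBRM-1 peaks far above the level after shifts. Of 612 tRNA genes, 440 (71.9%) had a summit within 500 bp, against 3.15% after shifts, with 58.2% in replicate 2 alone and 46.7% in replicate 1 alone. In 297 of the 612 loci a summit lay inside the tRNA gene itself. In all, 387 peaks (11.9% of the series list) lay within 500 bp of a tRNA gene, and their median signal was 122.9 against 89.5 for the other peaks. Small nuclear RNA genes had a nearby summit in 60 of 129 cases (46.5% against 3.27%), small nucleolar RNA genes in 129 of 346 (37.3% against 3.54%) and microRNA genes in 38 of 261 (14.6% against 3.24%). Each of these 4 had an adjusted permutation p of 0.0003, the smallest that 10000 shifts can give (two-sided permutation test, Benjamini-Hochberg over 6 classes). For microRNA genes the share was lower in replicate 1 alone (5.75% against 1.42% after shifts) and in replicate 2 alone (11.9% against 2.22%). The piRNA genes, which lie in dense clusters, had fewer nearby summits, 152 of 15363 (0.989% against 3.01%, adjusted permutation p = 0.00048). Ribosomal RNA genes had 1 of 20 (5% against 3.92%, adjusted permutation p = 0.934), but 7.14% of 70 strong peaks that are absent from the series list lay within 500 bp of one, so this count does not show a lack of signal there. tRNA genes occur in identical copies, so reads from them can be shared between loci. Other small RNA genes with several copies carry the same uncertainty. Whether nearby protein-coding promoters account for the summits was examined for tRNA genes only, so for the other classes it remains open.

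**Figure D4:**
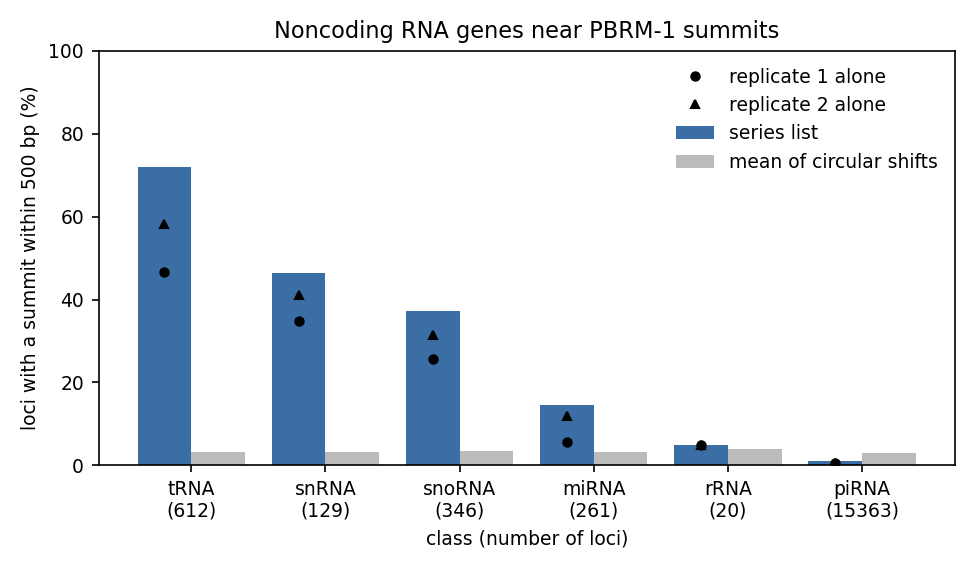
Percent of the loci of 6 noncoding RNA classes with a PBRM-1 summit within 500 bp (y axis), with the number of loci in parentheses. Blue bars are the series list, grey bars the mean of circular shifts and points each replicate alone; tRNA genes reach 71.9% against 3.15% after shifts, and piRNA genes lie below their shifted mean.

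Chromosome X differed from the autosomes in what its peaks lay on. On X, 194 of 509 peaks (38.1%) lay within 500 bp of a tRNA gene, against 7.06% on autosomes (Fisher's exact p = 5.51e-67), where X holds 276 of the 612 tRNA genes. Promoter windows held 34.4% of X summits against 55.4% of autosomal ones (Fisher's exact test, adjusted exact p = 1.05e-17 over 8 classes), where they cover 21.8% of X and 27.1% of the autosomes. Of 2731 protein-coding genes on X, 174 (6.37%) were bound, against 10.4% of 17242 autosomal genes (odds ratio 0.586, 95% interval 0.496 to 0.689, Fisher's exact p = 6.58e-12). X held 15.7% of all peaks (exact interval 14.5 to 16.99), against 17.7% of the bases (exact binomial p = 0.00297, two-sided). With the peaks near tRNA genes left out, X held 11.0% of peaks (exact p = 8.46e-23). The overall density on X was not stable: against its 13.7% share of protein-coding genes X held more peaks, not fewer (exact p = 0.000974), and no difference from the share of bases passed in the conservative list (16.4%), in the stronger peaks (17.6%), in replicate 2 alone (16.7%) or in replicate 1 alone (19.1%).

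Among the autosomes, III and I were the densest, with 41.4 and 40.3 peaks per Mb, and V, rich in chemoreceptor genes, was the sparsest with 24.5. II held 31.5 and IV 32.1, and X held 28.7. The central 50% of each of the 5 autosomes carried 39.6 peaks per Mb and the outer parts 26.6. The centres thus held 1636 of 2734 autosomal peaks (59.8%, exact interval 58.0 to 61.7), above 50% (exact binomial p = 6.81e-25, two-sided) and above their 55.7% share of protein-coding genes (exact p = 1.03e-05).

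Sequence at PBRM-1 summits was richer in GC than its surroundings. Within 100 bp of summits the GC content was 43.95% ± 7.29 (SD over 3243 peaks), against 37.4% ± 5.58 in flanks centred 600 bp away. The difference was 6.51 percentage points (SE 0.166), it was above 0 at 73.9% of peaks, and its p of 1e-05 is the smallest that 100000 sign flips can give (permutation test, two-sided). Of 18 motifs, 5 were found more often at summits than in flanks and 8 less often (exact McNemar tests, Benjamini-Hochberg). The GAGA repeat GAGAGAGA was found at 6.38% of summits against 1.73% of flank windows (3.70 times, adjusted exact p = 6.95e-22), the SP1-type box CCGCCC at 10.5% against 3.73% (2.80 times, adjusted exact p = 1.09e-27) and the E2F-type site TTSSCGC at 16.3% against 7.14% (2.29 times, adjusted exact p = 4.84e-26). The E-box CACGTG was at 5.92% against 3.87% (adjusted exact p = 1.99e-05). The DAF-16 site GTAAACA was at 3.39% against 2.33% (adjusted exact p = 0.00748), a call that was lost in each replicate alone, among the peaks at or above the median signal (1.26 times, adjusted exact p = 0.260) and without peaks near tRNA genes (1.31 times, adjusted exact p = 0.0643). Motifs found less often included the GATA site TGATAA (12.1% against 17.5%), the homeodomain core TAATTR (13.8% against 22.6%), the SKN-1 site (5.80% against 9.54%) and the ETS site CCGGAA (5.24% against 8.13%), with adjusted exact p from 2.52e-18 to 3.11e-05. These comparisons with flanks do not correct for base composition, and against windows shuffled with their dinucleotides kept the GATA site lay above the range of 20 shuffles and the SKN-1 site within it. Smaller deficits were found for the T-block, the heat shock element, the Inr-like site and the NF-Y box CCAAT (0.769, 0.786, 0.856 and 0.893 times the flanks). Against the shuffled windows, the T-block and the heat shock element lay above the range as well. The NF-Y deficit was lost in replicate 2 alone (adjusted exact p = 0.163) and without peaks near tRNA genes (adjusted exact p = 0.0736), and that of the heat shock element within 50 bp of summits (adjusted exact p = 0.165).

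Peaks in 1 replicate's list alone were weaker. There were 227 in replicate 1 and 1038 in replicate 2 with no overlap in the other list. The strongest of replicate 1 stood 375th in its own list (signal 84.8), beside 2 tRNA genes at II:3062154-3062437. Others of the 5 strongest lay in an intron of R107.5, in a 3' UTR where kel-8 and W02G9.3 overlap, nearest to duo-3, and by tRNA genes nearest to hil-3 on X. In replicate 2 the strongest stood 241st (signal 151), in the shared promoter of rpb-11, an RNA polymerase II subunit gene, and W01G7.4 at II:14059898-14060020. Next came the promoters of Y53F4B.9 and Y53F4B.11 (139), an intron of sre-45 beside a small nucleolar RNA gene (133), tRNA genes nearest to snt-7 on X (131), and the promoter of ash-2, a histone methyltransferase complex gene, and Y17G7B.20 (131). A peak missing from a replicate's list passed that list's threshold in the other replicate only, and no difference between replicates was tested.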

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

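The tests of motif composition and of strongly transcribed genes, and the use of the planned lists matched on spacing as a test of gene spacing, were chosen after the results they bear on were seen. The design has 1 group, so no biological explanation was tested for any of these patterns.

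In the series-level ranked list, 70 peaks had a score at or above the lowest of the series list yet were absent from it, and peaks outside the list used for the comparisons drew attention for that reason. They were strong, with a median signal of 115.8, and the strongest, at X:15810938-15811177 in intergenic sequence, reached 2300, above every peak of the series list. Of their bases 79.4% were soft-masked as repeats against 27.8% in the series list, 7.14% lay within 500 bp of a ribosomal RNA gene against 0.0308%, and 1.43% had promoter summits against 52.1%. Peaks left out of a list in this way numbered 61 for the conservative list, 52 for replicate 1 and 47 for replicate 2, and what those lie on was not examined.

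The summits near tRNA genes were weighed first. Identical copies share reads, which could place peaks at loci that were not bound. Among the 140 tRNA genes whose sequence occurs once, 50.7% still had a summit within 500 bp against 3.08% after shifts, and among the 276 lying over 1000 bp from promoter windows 69.9% did against 3.13% (each permutation p = 0.0002, the smallest the shifts can give). Nearby promoters are thus argued against as the whole cause. For shared reads the test cannot decide, because a summit within 500 bp can belong to a neighbouring tRNA gene of repeated sequence. Copies that differ slightly may also share reads. The higher share of 78.2% among repeated sequences leaves room for shared reads at some loci. Open chromatin at tRNA genes and a background of the antibody remain open, since no control data were used here.

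The bound ribosomal protein genes were weighed next. Lists matched on the distance to the upstream neighbour never reached 64 bound genes (permutation p = 2.00e-05, the smallest the draws can give), and neither did other rotations of the bound calls (p = 0.0001, the smallest they can give), which argues against gene spacing as the cause. Strong transcription in general may draw signal in such experiments, and here it cannot be told apart from a preference for these genes. Of 27 sarcomere and vitellogenin genes, 7 (25.9%) were bound, below the ribosomal 77.1% (Fisher's exact p = 3.53e-06) and above the 9.83% of other genes (Fisher's exact p = 0.0135). No excess over other genes passed in replicate 1 alone (7.41% against 4.62%, Fisher's exact p = 0.357) or in replicate 2 alone (7.41% against 7.63%). Nor did it pass in the peaks at or above the median signal (3.70% against 6.01%) or with narrower or wider promoter windows. It passed in the conservative list (Fisher's exact p = 0.0298) and with the q filter (0.0235). It also passed without peaks near tRNA genes (0.0104) and with nearest genes only (0.0035). Actin genes are among the 7 bound. Most of the 27 genes are active in few tissues of the whole worm, which keeps the question open.

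The motifs above the flanks were weighed last, since summits are richer in GC. Windows shuffled with their dinucleotides kept had a match in 2.03% for the GAGA repeat, 5.43% for the SP1-type box, 11.6% for the E2F-type site and 2.34% for the DAF-16 site, all under the observed 6.38%, 10.5%, 16.3% and 3.39%, and the excess was larger than in flanks, so composition is argued against as the whole cause for these 4. For the E-box the shuffled share was 3.63% against 5.92%, but the excess of 1.63 times was no larger than the 1.83 times in flanks, so its rise cannot be told apart from that of composition. Of the 8 motifs below the flanks, 4 (the homeodomain core, the ETS site, the NF-Y box and the Inr-like site) lay under the lowest of 20 shuffles. The NF-Y box stood at 0.925 times its shuffles at summits and 0.935 times in flanks, so its deficit cannot be told apart from that of flanks. The ratios at summits and in flanks were 0.830 and 0.908 for the homeodomain core, so flanks share part of its deficit. They were 0.635 and 1.31 for the ETS site, and 0.930 and 1.03 for the Inr-like site. Another 3 (the GATA site, the T-block and the heat shock element) lay above the highest shuffle, and the SKN-1 site lay within the range. The lower shares of these last sites do not show a deficit beyond composition. Ratios at summits and in flanks were 1.16 and 1.12 for the GATA site and 1.08 and 0.992 for the T-block. For the heat shock element they were 1.19 and 1.24. Of the 5 motifs that did not pass against flanks, 3 lay above the highest shuffle. Their ratios were 1.25 and 1.02 for the PHA-4 site TRTTKRY, 1.45 and 2.01 for CAGCTG, and 4.17 and 4.26 for TGACGTCA.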

How the results depend on the processing

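The caller q filter, the removal of peaks near tRNA genes and the count of bound genes by nearest gene were chosen after seeing the data. Of 571 values recomputed for 64 results, 528 were counted as unchanged. These passed in the same direction, did not pass under either setting, or stayed within their spread. Direction was not compared where neither value passed, so results such as body wall muscle genes count as unchanged although their direction turned. Of the 13 lists bound more often, 10 kept their call under every alternative run, as did 5 of the 8 bound less often: chemoreceptors, F-box and MATH-BTB genes, C-type lectins, neuropeptides and nuclear hormone receptors. The causes of the changes below were not tested. Vitellogenins without close followers gave no value, too few genes being left. Unknown read depth limits every absence of a peak, and lists from 1 replicate hold fewer peaks by construction.

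Without replicate 1 or 2, bound genes ranged from 924 to 1523, the X share of peaks from 16.7% to 19.1% (above the share of bases at its highest), and odds ratios from 2.70 to 5.59 for proteasome, 0.605 to 1.03 for insulin and TOR, 0.425 to 0.477 for collagens, 0 to 0.370 for sperm and 0.453 to 0.474 for detoxification genes. In the conservative list rho was 0.677 (0.334 over all ranked peaks), X held 16.4%, and odds ratios were 2.26 for proteasome, 3.17 for insulin and TOR and 0.309 for sperm genes. In peaks at or above the median signal, 1200 genes were bound, X held 17.6%, and odds ratios were 2.80 for proteasome, 1.65 for insulin and TOR, 0.455 for collagens and 0.613 for detoxification genes. Against its share of genes instead of bases, the 15.7% of peaks on X was an excess. With the q filter, odds ratios were 2.53 for insulin and TOR, 0.328 for sperm and 0.483 for detoxification genes, none passing. With the narrow window they were 3.68 for SWI/SNF and 0.373 for sperm genes, and with the wide window 0 for pharynx, now passing. With nearest genes only they were 0.367 for sperm and 0.541 for detoxification genes, and without close followers 0.442 for the latter, whose adjusted permutation p under rotation was 0.0695. Without peaks near tRNA genes, homeobox genes passed at 0.314.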

Other observations

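The count of spliced leader loci was chosen after its result was seen.

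The spliced leader genes, which supply the short exon that is trans-spliced onto worm messenger RNAs, include some of the strongest sites. Of 18 SL2 loci, 16 (88.9%) had a PBRM-1 summit within 500 bp. sls-2.4 and sls-2.1 lie beside 2 of the 4 strongest peaks. None of the 12 SL1 loci had a summit within 500 bp, but this count cannot be set against that of SL2. All SL1 loci lie between V:17118154 and V:17132107, in the cluster that also holds ribosomal RNA genes, and 4 of the 12 lay within 500 bp of one of the 70 strong peaks that are absent from the series list, so a lack of listed peaks there does not show a lack of signal. The other small nuclear RNA genes had a nearby summit in 44 of 99 cases.

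A hypothesis was that PBRM-1 marks the first genes of operon-like runs. Genes followed on the same strand within 500 bp, and not closely following another, were bound in 17.6% of 2516 cases, against 8.70% of 11443 genes with neither kind of close neighbour (odds ratio 2.24, 95% interval 1.98 to 2.53, Fisher's exact p = 1.01e-35). Close followers were bound in 8.80% of 6014 cases. The test is consistent with the hypothesis, but lists bound often, such as ribosomal protein genes, may also be common in operons, and this was not separated.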
